A study of Mus musculus with 12 samples.

How the data were processed

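RNA-seq was run on B16 F1 melanoma grown in the brain of C57BL/6 mice. B16 F1 is a pigmented mouse melanoma line. Per the labels' protocols, 100000 cells were implanted and tumors were taken at day 9. Tissue was lysed at once, RNA was extracted with the RNAqueous-Micro kit, and a NEBNext Ultra RNA library kit was used. Whether strand was used in counting is not given in the sources used here. The 12 libraries form 4 groups of 3, from tumor presence (intracranial tumor only, or intracranial and extracranial tumors) and treatment (IgG control antibody, or anti-PD-1 with anti-CTLA-4, called therapy here). The series text describes each group as biological triplicates. The labels give no batch, litter, day of processing or replicate number, so replicates were numbered in accession order, and no pairing was used.

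The count table holds raw reads per Ensembl gene, and the authors aligned reads with TopHat2 2.0.12 and Bowtie2 2.2.3 and counted them with HTSeq 0.6.1, per the submitters' processing notes, which name the builds GRCm38 and mm10. The annotation release is not given in the sources used here. A second table deposited by the authors holds FPKM values. For all 16062 genes with a read in every library, each FPKM equalled the count divided by 1 gene length and by the total count of the library, within a relative tolerance of 1e-06. Both tables have 47069 genes, of which 46488 identifiers matched a symbol and 581 did not. Coordinates come from an annotation of GRCm38. Members of gene families with near-identical copies, such as the H2-Q genes and the hemoglobin genes, can share reads, so their values are uncertain.

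Library totals ran from 18427495 to 22294182 reads. The most abundant gene, Dct, took 0.7552% to 1.113% of the reads, and mitochondrial genes took 0.4899% to 1.468%. Correlations of log2 CPM (counts scaled to library size, prior count 2) between replicates of a group lay between 0.917 and 0.986. The chi-square of their counts per degree of freedom lay between 16.02 and 100.6, so none of these 12 pairs within groups matched within sampling noise.

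The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, a fit of 4 group means over all 12 libraries, and the filter filterByExpr (minimum count 10, minimum total 15). It kept 15925 genes, which held at least 99.87% of the reads of every library. The common dispersion was 0.112, a biological coefficient of variation of 33.5%. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. There were 5 comparisons: therapy against IgG in mice with both tumors, therapy against IgG in mice with the intracranial tumor only, both tumors against intracranial only under IgG, the same under therapy, and the interaction, which is the difference between both therapy effects. Standard errors of log2 fold changes were derived from the test, as the absolute log2 fold change divided by the square root of its F statistic.

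Before the data were examined, 30 gene lists were fixed for immune cells, antigen presentation, trafficking, tumor cells and other cells a dissected brain tumor can hold. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. The B and plasma cell, choroid plexus and ependyma, and skeletal muscle lists had fewer than 5 tested genes, so 27 were tested. Camera compares a list with all other genes. Its sign can differ from that of the list's median log2 fold change. Such fold changes come from group means of counts, in which 1 high library weighs more than in a mean of log2 values. Each call was computed again with a correlation estimated per list and with fry, which tests whether a list's genes move one way on balance. Some genes, such as Icam1, Ccl5 and Ccr7, stand in more than 1 list, and 2 symbols were matched through a synonym.

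Named genes followed a rule fixed in advance. It took the 10 higher and 10 lower genes with the largest fold change among those past the threshold, with a mean of at least 1 CPM in a group and no overlap between the 3 libraries of each group (5 and 5 for the interaction, without the last condition). It also took up to 3 members with the smallest p of each list past its threshold, and 20 genes reported in every comparison. Unnamed gene models and receptor segments were left out, and some genes that meet the rule are not reported here. Where a gene had 0 reads in a group, a bound was computed against 3 reads over the group. With 1 to 3 reads, the ratio is given with a 95% interval. Bounds and intervals cover counting error only.

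The test was checked on simulated counts drawn from the real means and library sizes, with 200 changed genes among 15653. Of the genes changed 2-fold and 4-fold it recovered 35% and 73% for therapy in mice with both tumors, 29% and 71% for the extracranial tumor under therapy, and 9% and 54% for the interaction. With no change simulated, 0 genes were called in each of these comparisons, and 0, 1 and 0 lists. Genes were drawn independently of each other, so this check cannot show how the gene counts and list tests behave when genes are correlated.

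The alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0, limma voom with sample weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fit of the compared groups alone, the mean of the neuron list as a covariate, and leaving out each library in turn. A robust edgeR fit and the mean of the neuron, oligodendrocyte and astrocyte lists as a covariate were added after seeing the data. Splits of the libraries into other groups of 3 were counted for each comparison.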

Results

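The data are gene-level read counts from 12 intracranial B16 F1 tumors at day 9, in 4 groups of 3 libraries. Total counts per library ran from 18427495 to 22294182. The series asks whether the effect of anti-PD-1 with anti-CTLA-4 on melanoma in the brain depends on melanoma outside the brain. Groups are called by tumor presence (both tumors, or intracranial only) and by antibody (therapy, or IgG). The first principal component of log2 CPM held 70.9% of the variance and the second 13.6%. On the first, the therapy libraries of mice with both tumors lay at 61.58, 137.5 and 123.7 and the therapy libraries of intracranial-only mice at -103.6, -113 and -95.04. Replicate 2 of the IgG mice with both tumors lay at -115.1, beside the second of these groups, while its own replicates lay at 35.62 and 54.65. The sample name of this library in the labels ends in a suffix that differs from that of the other libraries, and its meaning is not given in the sources used here.

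Therapy against IgG in mice with both tumors asks what treatment changed in the brain tumor when melanoma was also present elsewhere. The proliferation marker Mki67 fell, changing by -1.56 ± 0.39 (log2 fold change ± SE, n = 3 per group), from 236 ± 60.7 to 80.2 ± 44.4 CPM (mean ± SD). Foxp3, the master transcription factor of regulatory T cells, rose by 2.43 ± 0.57, from 0.458 ± 0.297 to 2.50 ± 0.287 CPM. The central complement gene C3 rose by 2.42 ± 0.52, the inducible nitric oxide synthase gene Nos2 by 4.42 ± 0.95 and the eosinophil-attracting chemokine gene Ccl11 by 3.75 ± 0.53. Each of these genes had an adjusted p = 0.0498 in edgeR's quasi-likelihood test. No gene passed with RLE size factors, without the filter, in a fit of both compared groups alone, with the neuron list as a covariate, or when any of 9 of the 12 libraries was left out. Pmel, a melanosome gene that marks the tumor cells, was at 0.24 ± 0.18 (adjusted p = 0.336).

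Cytotoxic T cell genes were higher in the therapy libraries but did not pass the gene-wise test. Cd8a, a coreceptor chain of cytotoxic T cells, averaged 17.3 ± 8.35 CPM with therapy and 1.38 ± 1.10 CPM with IgG (3.63 ± 1.37, adjusted p = 0.102). Values for the granzyme gene Gzmb were 3.58 ± 2.04 (adjusted p = 0.23), for Ifng 3.96 ± 1.77 (adjusted p = 0.147) and for Pdcd1, which encodes PD-1, 3.08 ± 1.30 (adjusted p = 0.13). Vcam1, an endothelial adhesion molecule for leukocytes, was at 2.68 ± 0.86 (adjusted p = 0.0727). In each of these groups n = 3. Cd8a (ENSMUSG00000053977) lies on chromosome 6 of GRCm38 from 71373427 to 71379173, Foxp3 (ENSMUSG00000039521) on chromosome X from 7573644 to 7595245, Mki67 (ENSMUSG00000031004) on chromosome 7 from 135689784 to 135716361 and Snap25 (ENSMUSG00000027273) on chromosome 2 from 136713453 to 136782428.

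**Figure D1:**
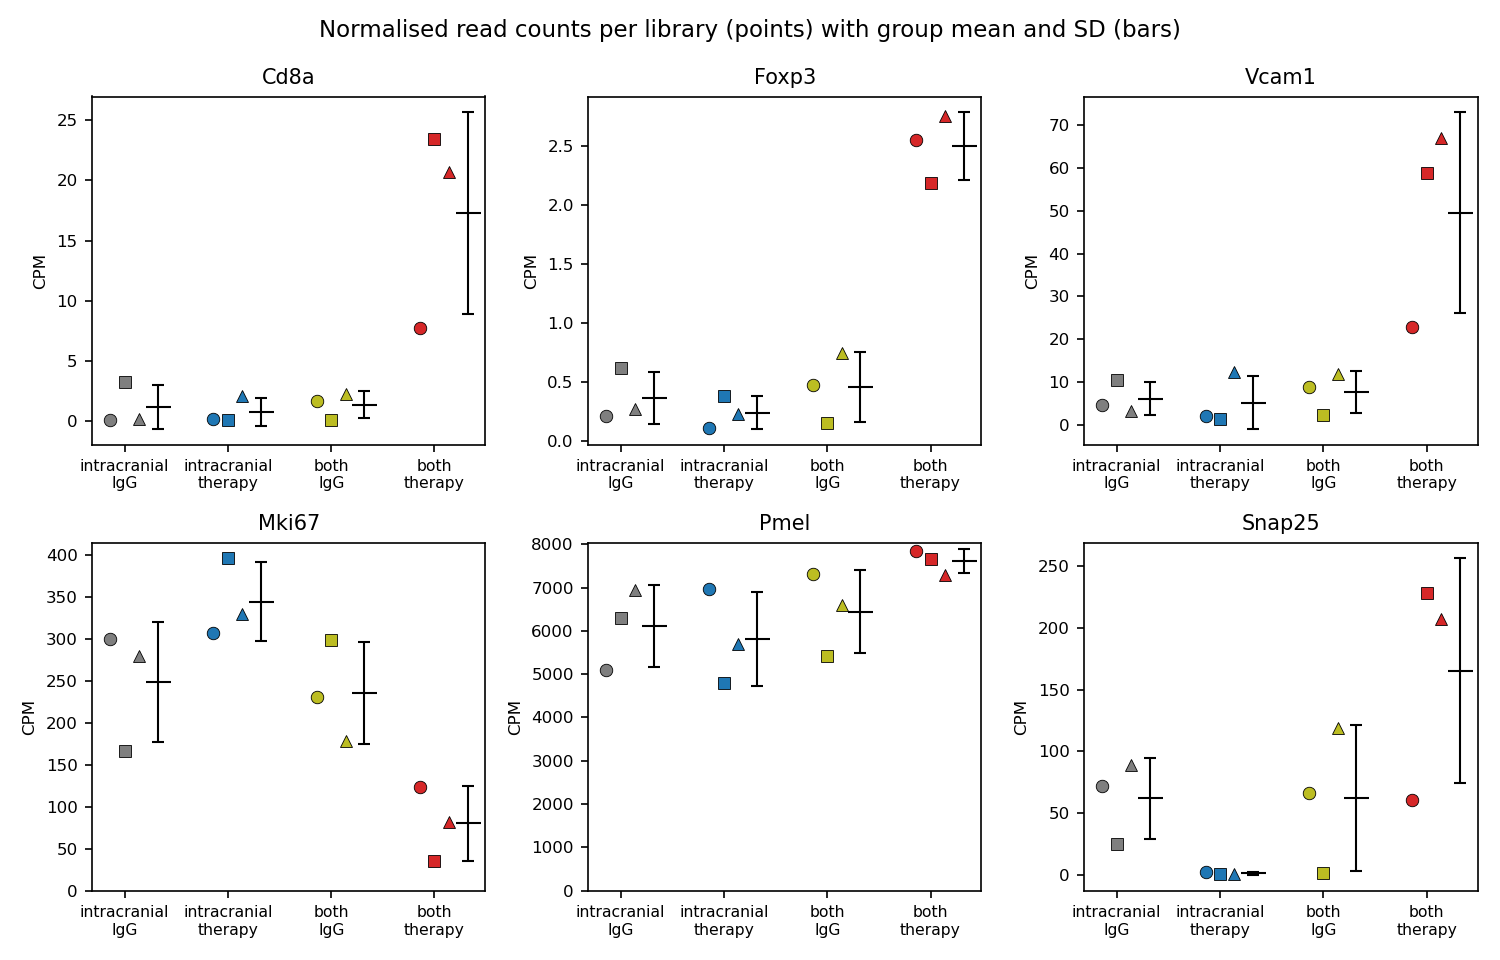
CPM of 6 genes (vertical axes) in the 12 libraries, by group, with 1 point per library, marker shape for the replicate, and bars for the group mean and SD. The therapy libraries of mice with both tumors reach 7.77, 23.4 and 20.7 CPM for Cd8a and 124, 35.2 and 81.4 CPM for Mki67, while Snap25 lies at 2.16 CPM or less in the therapy libraries of intracranial-only mice.

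As groups, 21 of the 27 tested lists were higher with therapy in mice with both tumors, and 1, cell cycle, was lower. With RLE size factors 20 lists passed, and the dendritic cell and endothelial adhesion lists did not (adjusted p = 0.0586 and 0.0536). The T cell identity list had a median log2 fold change of 2.67 (adjusted p = 4.15e-05), with 0 of its 16 genes past the gene-wise threshold and 1 when adjusted over the list alone. The checkpoint receptor list (median 2.35, adjusted p = 6.28e-05) had 1 of 12 past it, Layn, which encodes a hyaluronan receptor, and 5 adjusted over the list alone. Of the regulatory T cell list (2.01, adjusted p = 7.65e-05), Foxp3 and the costimulatory receptor gene Tnfrsf18 (2.13 ± 0.51) rose and 6 of 8 passed when adjusted over the list alone. The cytotoxic effector (2.89, adjusted p = 0.00113), interferon gamma response (2.39, adjusted p = 2e-04), type I interferon response (1.69, adjusted p = 0.00136), MHC class I (2.14, adjusted p = 0.000141), MHC class II (3.14, adjusted p = 0.00139) and chemokine (2.53, adjusted p = 0.000141) lists had 0 genes past the gene-wise threshold, and 0 adjusted over the list alone. Complement (2.42, adjusted p = 1.4e-06) had 2 of 11, C3 among them, and 11 adjusted over the list alone. Monocyte and macrophage genes (1.82, adjusted p = 7.65e-05) had 2 of 14, Nos2 and Cd68, and 8 adjusted over the list alone. The cell cycle list (-1.47, adjusted p = 4.22e-17) had 11 of 20 genes lower and all 20 adjusted over the list alone, among them Ccnb1 at -1.82 ± 0.40 and Top2a at -1.31 ± 0.31. With an estimated correlation none of the 22 calls held. The values were adjusted p = 0.455 for T cell identity and the chemokines, adjusted p = 0.469 for the cytotoxic and both MHC lists. They were adjusted p = 0.485 for interferon gamma, adjusted p = 0.525 for type I interferon and adjusted p = 0.358 for the checkpoint, regulatory T cell, complement, macrophage and cell cycle lists. The fry test called 8 lists.

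Brain-tissue markers moved the same way as these immune groups. The oligodendrocyte list had a median of 2.23 (adjusted p = 1.54e-06; adjusted p = 0.358 with an estimated correlation), with Cnp and Ugt8a rising and 11 of 11 genes passing when adjusted over the list alone. The astrocyte list stood at 1.47 (adjusted p = 6.28e-05; 0.358 as an adjusted p with an estimated correlation) and the neuron list at 1.39 (adjusted p = 0.00196; 0.469 likewise). Without both-tumor IgG replicate 2, whose neuron score was -0.39 against 4.56 and 5.02 in its group, the neuron list had a median of 0.82 (adjusted p = 0.0294). Homeostatic microglia genes, those of resting brain macrophages, had a median of 1.78 (adjusted p = 7.65e-05; 0.358 likewise), with Olfml3 at 1.96 ± 0.39. Immediate early genes (1.14, adjusted p = 0.00222; 0.358 likewise) included Egr1 at 2.13 ± 0.52 and Jun at 1.72 ± 0.29. The endothelial cell list was at 0.56 (adjusted p = 0.0149; 0.406 likewise). The melanocyte list, at -0.07, did not pass (adjusted p = 0.901), and neither did hypoxia and glycolysis at -0.07 (adjusted p = 0.814), pericyte and fibroblast at 0.54 (adjusted p = 0.566) or red blood cell at 0.22 (adjusted p = 0.689). Of the lists too small to test, the B and plasma cell genes had a median of 2.11 over 3 genes, choroid plexus and ependyma 0.67 over 4 and skeletal muscle -0.75 over 3.

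Gene by gene, 858 of 15925 genes passed, 198 higher and 660 lower, with 23.1% higher. The largest increases included Ccl24 (6.08 ± 1.44), another eosinophil-attracting chemokine gene, Apol7c (4.46 ± 0.86), the neurotensin gene Nts (3.58 ± 0.66) and the B cell survival factor gene Tnfsf13b (3.37 ± 0.85). The largest decreases included Hapln1 (-2.59 ± 0.63), a link protein of hyaluronan matrix, Mgam (-2.45 ± 0.61) and the prokineticin receptor gene Prokr1 (-2.30 ± 0.47). The smallest adjusted p was 0.0498. The libraries without which the count was 0 were intracranial-only IgG replicates 1 and 3, intracranial-only therapy replicates 1, 2 and 3, both-tumor IgG replicates 1 and 2 and both-tumor therapy replicates 2 and 3. In turn 2064 passed without both-tumor IgG replicate 3 and 2394 without both-tumor therapy replicate 1. DESeq2 called 3139 genes with 43.6% higher, voom 5527 with 54.3%. Counts were, for log2(FPKM + 1), 2630 with 46% and, for log2(FPKM + 0.1), 1759 with 30.9%. Unadjusted p-values under 0.05 were found for 5317.

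Several list calls in this comparison depended on 1 library. The dendritic cell list (median 1.19, adjusted p = 0.0485; 0.485 with an estimated correlation) did not pass without intracranial-only therapy replicate 1 (0.0537), 2 (0.0504) or 3 (0.0521). The same held for both-tumor IgG replicate 2 (0.0814) and 3 (0.093) and both-tumor therapy replicate 1 (0.117). Endothelial adhesion genes (1.19, adjusted p = 0.0478; 0.358 likewise) did not pass without both-tumor therapy replicate 3 (0.0507) and, with the neuron covariate, stood at 0.0577. Leukocyte homing receptors (1.51, adjusted p = 0.0429; 0.455 likewise) did not pass without both-tumor IgG replicate 2 (0.0914) or 3 (0.0824) or both-tumor therapy replicate 1 (0.0664) or 3 (0.0507). The neutrophil list (2, adjusted p = 0.0202; 0.358 likewise) did not pass without both-tumor therapy replicate 1 (0.0507) or 2 (0.0591). The endothelial cell list did not pass without both-tumor therapy replicate 1 (0.0633) or 3 (0.0507). The NK cell list (1.82, adjusted p = 0.0851) passed without intracranial-only IgG replicate 1 (0.0195), 2 (0.00657) or 3 (0.0201). It also passed without intracranial-only therapy replicate 1 (0.0264), 2 (0.0269) or 3 (0.0177), both-tumor IgG replicate 1 (0.0168) or both-tumor therapy replicate 3 (0.0316).

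**Figure D2:**
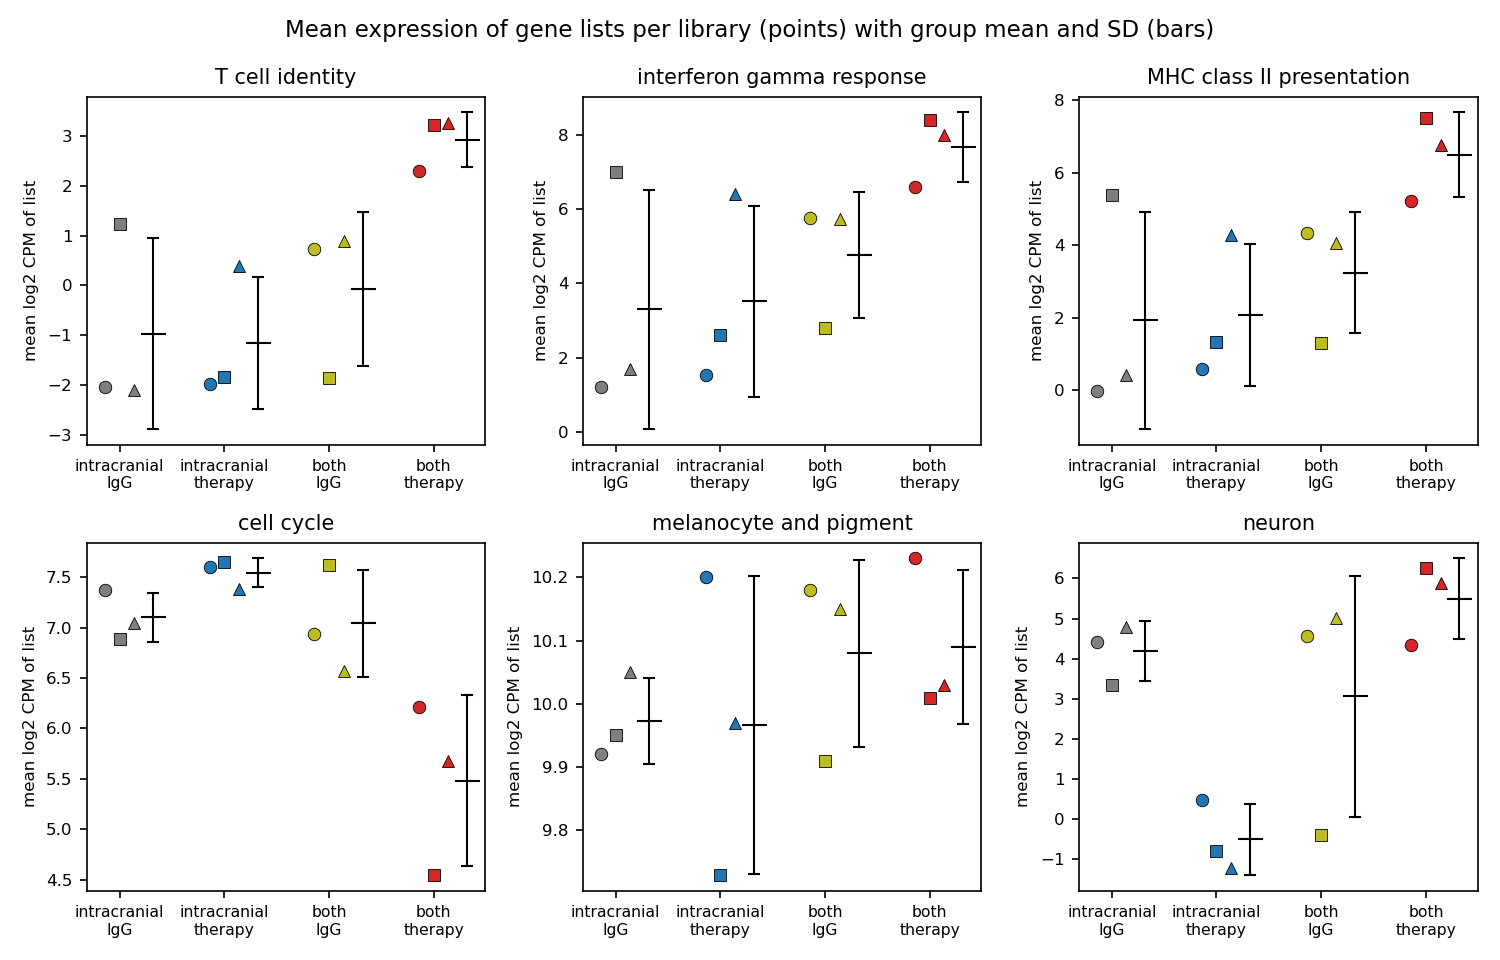
Mean log2 CPM of 6 gene lists (vertical axes) in the 12 libraries, by group, with 1 point per library, marker shape for the replicate, and bars for the group mean and SD. The T cell identity list lies at 2.30, 3.22 and 3.27 in the therapy libraries of mice with both tumors, and the neuron list lies at 0.48, -0.78 and -1.21 in the therapy libraries of intracranial-only mice and at -0.39 in replicate 2 of the IgG mice with both tumors.

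Therapy against IgG in mice with the intracranial tumor only asks the same question without melanoma elsewhere. Here the brain-tissue lists were lower with therapy. The neuron list had a median of -5.15 (adjusted p = 1.68e-16; adjusted p = 0.396 with an estimated correlation), with group means of -0.50 ± 0.88 with therapy and 4.19 ± 0.75 with IgG (mean log2 CPM ± SD, n = 3). The synaptic gene Snap25 was at -5.94 ± 1.39 (adjusted p = 0.134), from 61.9 ± 33.0 to 1.02 ± 0.990 CPM, and Gfap, an astrocyte filament gene, at -3.71 ± 0.73 (adjusted p = 0.134). T cell genes did not pass: Cd8a was at -0.57 ± 1.33 (adjusted p = 0.893) and the T cell identity list at -0.68 (adjusted p = 0.998). Without intracranial-only IgG replicate 2 that list turned and passed as higher (adjusted p = 0.000238).

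The oligodendrocyte list had a median of -4.34 (adjusted p = 4.91e-09), or -2.53 with its low-read genes at their bound, and the astrocyte list a median of -2.08 (adjusted p = 4.91e-09). None of the genes of these lists passed gene-wise. Adjusted over the list alone, 12 of 12 neuron, 7 of 11 oligodendrocyte and 7 of 12 astrocyte genes did. The myelin gene Mog had 1 read with therapy and 102 with IgG, a ratio of 104 (18.2 to 4140). Microglia genes were lower (-1.71, adjusted p = 2.45e-05, 2 of 11 adjusted over the list alone), for example Siglech at -3.67 ± 1.15 (adjusted p = 0.168), as were the endothelial cell (-0.36, adjusted p = 0.0275) and red blood cell (-2.52, adjusted p = 0.0444) lists. Cell cycle genes were higher by a median of 0.44 (adjusted p = 3.86e-05), all 20 fitted above 0. Mki67 was at 0.47 ± 0.39 (adjusted p = 0.658). With an estimated correlation none of the 7 list calls held: adjusted p = 0.396 for neuron, oligodendrocyte and astrocyte, adjusted p = 0.731 for microglia, adjusted p = 0.818 for endothelial cells and adjusted p = 0.999 for the red blood cell and cell cycle lists. Pigment genes did not pass (-0.02, adjusted p = 0.8064).

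In edgeR 0 genes passed, with 2151 at an unadjusted p under 0.05 and a smallest adjusted p = 0.134. DESeq2 called 1038, of which 1008 were lower. A fit of both compared groups alone called 839, of which 824 were lower. In turn 1002 passed without both-tumor IgG replicate 2, and voom and both FPKM fits called 0. With the neuron covariate the cell cycle list turned lower (adjusted p = 0.00622), the microglia list did not pass and turned higher (0.305), and the oligodendrocyte, astrocyte and endothelial cell lists did not pass (0.244, 0.807 and 0.244). Without intracranial-only IgG replicate 2, 11 immune lists passed as higher: interferon gamma, type I interferon and MHC class I (adjusted p = 2.59e-08, 9.21e-06 and 2.47e-07), T cell identity (0.000238), cytotoxic effector (6.77e-05), MHC class II and chemokines (8.55e-05 each), macrophage (0.000111), NK cell (0.00276), dendritic cell (0.00987) and homing receptors (0.026). Without intracranial-only therapy replicate 3 the first 3 of these passed as lower (0.0245, 0.00156 and 0.0184). Complement passed as lower without that library (0.00534) or intracranial-only IgG replicate 1 (0.0414) or 3 (0.00475), and hypoxia and immediate early genes without intracranial-only therapy replicate 2 (2.95e-07 and 0.00103). The endothelial list did not pass without intracranial-only IgG replicate 3 (0.0542), therapy replicate 1 (0.0897) or 3 (0.0593) or both-tumor IgG replicate 2 (0.11). The red blood cell list did not pass without intracranial-only IgG replicate 1 (0.334) or 3 (0.0525), therapy replicate 1 (0.0897) or 3 (0.177), both-tumor IgG replicate 2 (0.271) or both-tumor therapy replicate 1 (0.0535).

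Both tumors against intracranial only under IgG asks what an extracranial tumor changed in the untreated brain tumor. Hypoxia and glycolysis genes were lower with both tumors, by a median of -0.95 (adjusted p = 1.46e-24; 0.209 as an adjusted p with an estimated correlation), with all 12 genes fitted below 0. The angiogenic factor gene Vegfa was at -1.30 ± 0.47 (adjusted p = 1), from 129 ± 13.6 to 52.4 ± 17.9 CPM (n = 3 per group), and the vasodilator peptide gene Adm at -0.91 ± 0.32 (adjusted p = 1). Red blood cell genes were lower by a median of -2.88 (adjusted p = 6.8e-10; 0.216 likewise), for example the hemoglobin gene Hbb-bs at -3.13 ± 1.24 (adjusted p = 1). Immediate early genes were lower too, at -0.46 (adjusted p = 0.000309; 0.262 likewise). The neuron list was lower with a median of -0.04 (adjusted p = 0.0207; 0.682 likewise), and the endothelial cell list with one of -0.25 (adjusted p = 0.00398; 0.522 likewise). Neuron scores were 4.56, -0.39 and 5.02 with both tumors and 4.41, 3.35 and 4.8 without the extracranial tumor, so that call rested on both-tumor IgG replicate 2.

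Lists called higher had small medians in this comparison, in which 1 library of each group stood apart in immune lists. The interferon gamma score, for example, was 1.2, 7.01 and 1.7 in the intracranial-only IgG libraries and 5.77, 2.8 and 5.73 with both tumors. The dendritic cell list was at 0.53 (adjusted p = 0.000289; 0.522 with an estimated correlation), T cell identity at 0.36 (adjusted p = 0.000309; 0.682 likewise), the pigment list at 0.08 and leukocyte homing receptors at 0.06 (both adjusted p = 0.0207; 0.682 likewise). Camera called 6 further lists higher whose medians lay below 0: cytotoxic effector (-0.36, adjusted p = 0.0207), NK cell (-0.06, adjusted p = 0.0218), interferon gamma response (-0.07, adjusted p = 0.00151), MHC class I (-0.15, adjusted p = 0.0207), MHC class II (-0.36, adjusted p = 0.0167) and chemokines (-0.28, adjusted p = 0.0423). Their mean log2 CPM was higher with both tumors, for example -0.03 ± 1.51 against -0.89 ± 2.65 for cytotoxic effector (mean ± SD). For MHC class II it was 3.24 ± 1.68 against 1.93 ± 2.99. The median log2 fold change over all genes was 0.01, and fry also had these lists higher without passing (adjusted p = 0.9496). The adjusted p with an estimated correlation was 0.682 for cytotoxic effector, NK cell, interferon gamma and MHC class II and 0.704 for MHC class I and chemokines. No gene of any list passed, and 0 did adjusted over the list alone. Without intracranial-only IgG replicate 1 all 10 lists lost their calls (adjusted p from 0.134 to 0.984), as all 10 did without both-tumor IgG replicate 1 (0.0608 to 0.839). All but the pigment list did without intracranial-only IgG replicate 3 (0.101 to 0.964), and all but the dendritic cell list without both-tumor IgG replicate 3 (0.137 to 0.742). The pigment list also did without intracranial-only IgG replicate 2 (0.0692). Chemokines did without intracranial-only therapy replicates 1, 2 and 3 (0.305, 0.196 and 0.193) and both-tumor therapy replicates 1 and 3 (0.239 and 0.228). Other calls were gained. Without intracranial-only IgG replicate 2, 6 lists passed that had not with all libraries, and 8 did so with direction kept without both-tumor IgG replicate 2. Over the fits without 1 library the lowest adjusted p was 1.83e-29 for interferon gamma and 4.44e-23 for type I interferon. With RLE size factors chemokines did not pass (0.0904), and the astrocyte list, at a median of -0.1 and adjusted p = 0.0597, passed as lower (0.0486).

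In edgeR 0 genes passed, with 188 at an unadjusted p under 0.05, and DESeq2, voom and both FPKM fits also called 0. The neuron list lost its call without intracranial-only IgG replicate 1 (0.17) or 3 (0.534) and turned higher without both-tumor IgG replicate 2 (0.0094). Oligodendrocyte and astrocyte lists also turned without the latter library and passed as higher (0.0352 and 0.0376). Without both-tumor IgG replicate 3 microglia genes turned and passed as lower (0.0021), and cell cycle genes as higher (0.00557). Macrophage genes did as lower without intracranial-only IgG replicate 3 (0.0415). The endothelial list lost its call without intracranial-only IgG replicate 3 (0.0779) or both-tumor IgG replicate 2 (0.18).

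Both tumors against intracranial only under therapy asks whether treated brain tumors differed with melanoma elsewhere. By list, 18 of the 27 tested lists were higher with both tumors, among them T cell identity, complement, microglia and neuron, and 2, cell cycle and hypoxia, were lower. None of these calls held with an estimated correlation (adjusted p = 0.541 for each). Cd8a was higher by 4.40 ± 1.43 (adjusted p = 0.0288), from 0.798 ± 1.14 to 17.3 ± 8.35 CPM (n = 3 per group), Foxp3 by 3.34 ± 0.61 (adjusted p = 0.00455) and Vcam1 by 3.22 ± 0.89 (adjusted p = 0.0145). Mki67 fell by 2.10 ± 0.40 (adjusted p = 0.00458), from 345 ± 46.4 to 80.2 ± 44.4 CPM. Snap25 was higher by 7.36 ± 1.45 (adjusted p = 0.00469), from 1.02 ± 0.990 to 165 ± 90.9 CPM, and P2ry12, a microglial receptor gene, by 3.66 ± 0.67 (adjusted p = 0.00455). Pmel was at 0.39 ± 0.18 (adjusted p = 0.0954) and the pigment list at 0.07 (adjusted p = 0.8065).

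Of the T cell identity list (median 4.02, adjusted p = 0.000319) 13 of 16 genes rose, and 14 adjusted over the list alone. Checkpoint receptors (3.12, adjusted p = 0.000336) rose in 11 of 12 and 12 adjusted over the list alone, among them Pdcd1 (4.81 ± 1.44, adjusted p = 0.0204) and Ctla4 (4.87 ± 1.64, adjusted p = 0.0334). Regulatory T cell genes (2.60, adjusted p = 0.00186) rose in 7 of 8 by both counts, and Ccr8, a chemokine receptor gene of such cells, had 2 reads against 100, a ratio of 45.4 (12.3 to 380). Of the cytotoxic effector list (3.87, adjusted p = 0.00803) 4 of 13 rose, with 2 adjusted over the list alone, while Gzmb was at 3.55 ± 2.03 (adjusted p = 0.174). Complement (2.78, adjusted p = 3.02e-05) rose in 11 of 11 by both counts. So did chemokines (3.15, adjusted p = 0.00209) in 7 of 18 with 6 adjusted over the list alone. Macrophage genes (2.60, adjusted p = 0.00799) rose in 7 of 14 by both counts and dendritic cell genes (2.86, adjusted p = 0.0258) in 4 of 10 by both counts. Interferon and antigen presentation lists passed with few members: interferon gamma (2.73, adjusted p = 0.0029) with 1 of 20, type I interferon (2.31, adjusted p = 0.00565) with 0 of 20, MHC class I (2.52, adjusted p = 0.00209) with 2 of 18 and MHC class II (3.80, adjusted p = 0.00922) with 3 of 10. Adjusted over the list alone these counts were 0, 0, 0 and 2. Every list called in this comparison stood at adjusted p = 0.541 with an estimated correlation, and fry called 17 lists. Leukocyte homing receptors (2.48, adjusted p = 0.0635), endothelial adhesion genes (2.11, adjusted p = 0.0687), NK cell (2.99, adjusted p = 0.0687) and neutrophil genes (1.81, adjusted p = 0.206) did not pass as lists. Without intracranial-only IgG replicates 1, 2 and 3 the NK cell list passed (0.0233, 0.00802 and 0.0247), as did adhesion genes (0.0355, 0.0278 and 0.038) and homing receptors (0.0355, 0.0191 and 0.0421). NK cell also passed without intracranial-only therapy replicate 3 (0.00738), both-tumor IgG replicate 1 (0.042) or both-tumor therapy replicate 3 (0.0344), and homing receptors without intracranial-only therapy replicate 3 (0.0383) or both-tumor therapy replicate 2 (0.0404). Adhesion genes also passed without intracranial-only therapy replicate 2 (0.0427) or 3 (0.0295) or both-tumor IgG replicate 1 (0.045) or 2 (0.0451), and neutrophil genes without both-tumor therapy replicate 3 (0.014).

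Brain markers moved with those immune groups. The neuron list (6.66, adjusted p = 1.24e-06) rose in 12 of 12 genes and the oligodendrocyte list (6.57, or 5.82 with low-read genes at their bound, adjusted p = 2.41e-07) in 11 of 11. The astrocyte list (3.62, adjusted p = 2.06e-06) rose in 11 of 12 and the microglia list (3.66, adjusted p = 1.06e-05) in 10 of 11, with the same counts adjusted over the list alone. Endothelial cell genes (0.80, adjusted p = 0.02625) rose in 7 of 13 and fell in 1, with the tight junction gene Cldn5 at 3.32 ± 0.69 (adjusted p = 0.00512). The 10 largest named increases were genes with 0 reads in the intracranial-only therapy group, among them the long noncoding RNA Miat (at least 259-fold higher), the glutamate receptor auxiliary gene Cnih3 (at least 155-fold) and the calcium-binding protein gene Calb1 (at least 129-fold). Cell cycle genes (-1.88, adjusted p = 8.03e-15) fell in 20 of 20, and of the hypoxia list (-0.86, adjusted p = 0.02625) 4 of 12 fell, with 3 adjusted over the list alone, such as the carbonic anhydrase gene Car9 (-2.23 ± 0.60, adjusted p = 0.013). Immediate early genes (1.09, adjusted p = 0.0405) rose in 5 of 11 and fell in 1, with 6 and 1 adjusted over the list alone. Btnl9 had 2 reads with both tumors against 75, a ratio of 41.3 (11 to 347).

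In all 7231 genes passed, 3886 higher and 3345 lower, and 0 did with the neuron covariate. The count was 4710 without both-tumor therapy replicate 2. The calls of Cd8a, Ctla4 and Pdcd1 were lost without intracranial-only therapy replicate 1 (adjusted p = 0.0873, 0.0957 and 0.067) or 2 (0.086, 0.103 and 0.0707) or both-tumor therapy replicate 2 (0.0725, 0.0833 and 0.0537). Lost too were those of Cd8a and Ctla4 without both-tumor therapy replicate 3 (0.0627 and 0.0641), that of Vcam1 without intracranial-only therapy replicate 1 (0.0512) and that of Car9 without both-tumor therapy replicate 2 (0.0528). Of the list calls, dendritic cell was lost without both-tumor therapy replicate 1 (0.0512). Endothelial cell was lost without intracranial-only therapy replicate 3 (0.0541) or both-tumor therapy replicate 1 (0.0694) or 3 (0.0624). Hypoxia was lost without intracranial-only therapy replicate 2 (0.446) or both-tumor therapy replicate 1 (0.0694) and turned with the neuron covariate (0.507). Immediate early was lost without intracranial-only therapy replicate 1 (0.0923) or 3 (0.0696) or both-tumor IgG replicate 2 (0.0869) or 3 (0.0513).

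**Figure D3:**
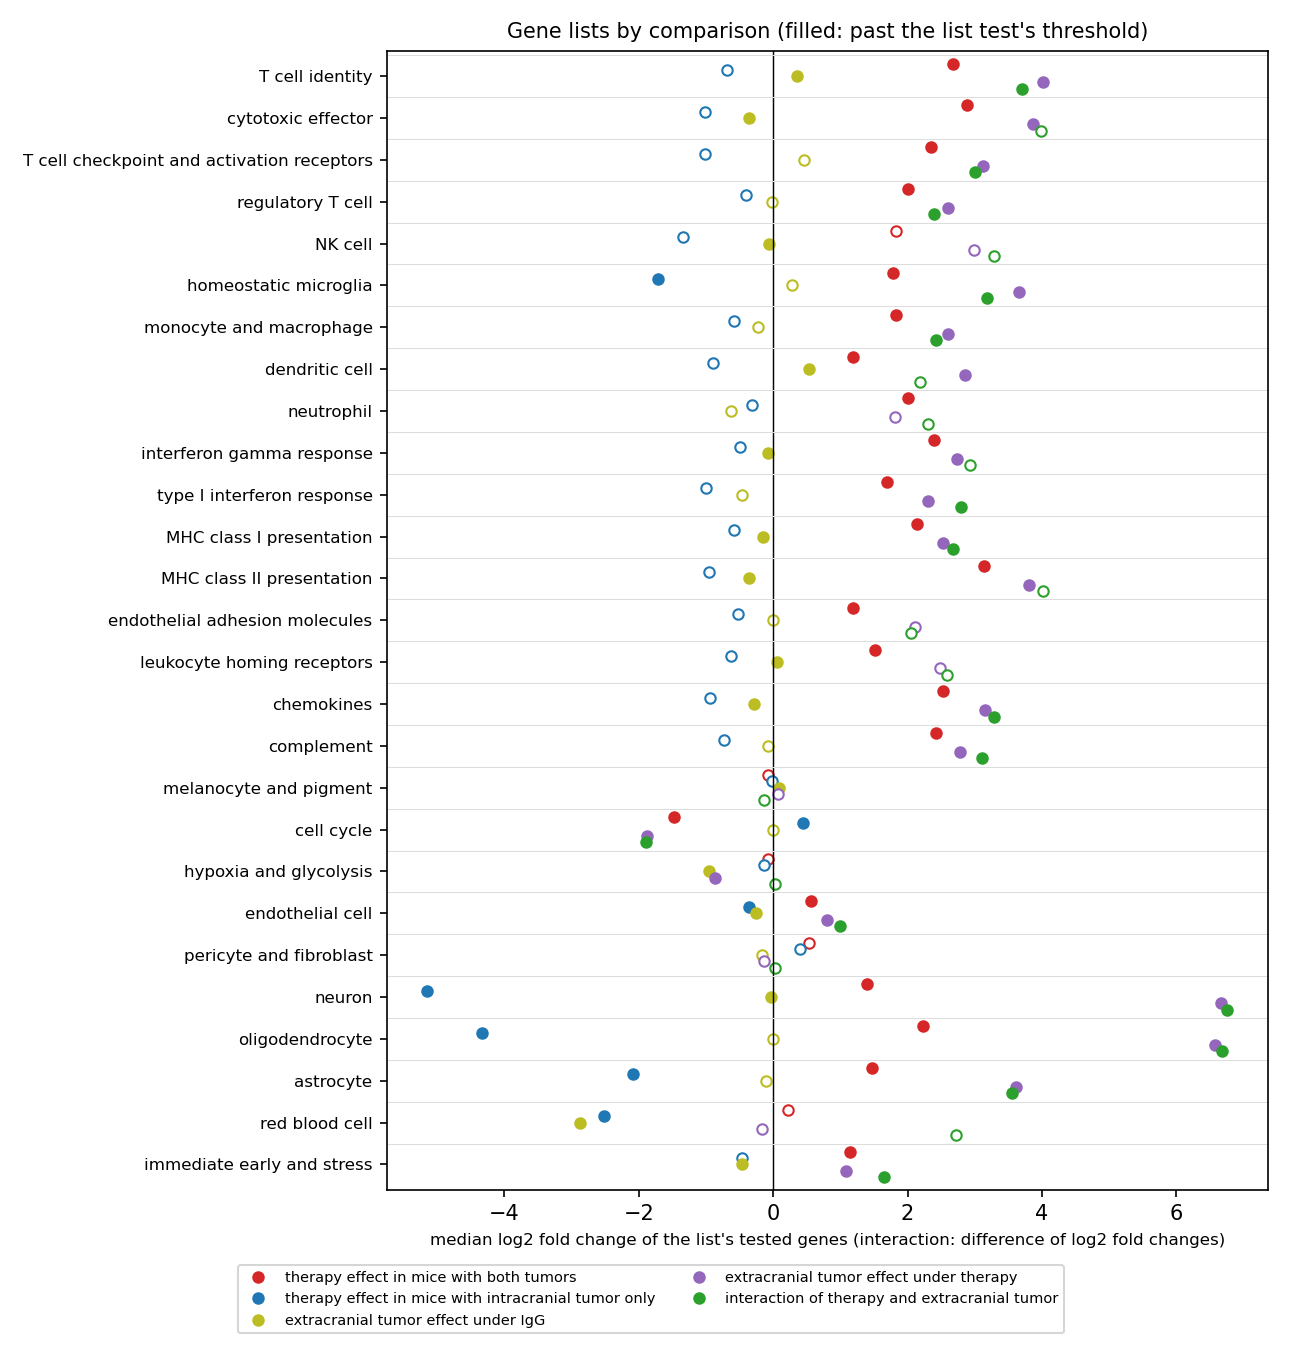
Median log2 fold change (horizontal axis) of the 27 tested gene lists (vertical axis) in the 5 comparisons, shown by color, with filled points for lists past the threshold of the list test. The neuron list lies at 6.66 for the extracranial tumor under therapy and at -5.15 for therapy in intracranial-only mice, and the cell cycle list lies at -1.88 and 0.44.

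The interaction asks whether the effect of therapy itself differed between both tumor settings. The neuron, oligodendrocyte, astrocyte and microglia lists had a therapy effect that was higher with both tumors than without the extracranial tumor, and the cell cycle list had a lower one. None of these calls held with an estimated correlation (adjusted p = 0.41 for each), and 0 genes passed when any of 8 of the 12 libraries was left out. The difference of log2 fold changes was 7.35 ± 1.74 for Snap25 (adjusted p = 0.0321), 3.07 ± 0.88 for P2ry12 (adjusted p = 0.0376), 3.02 ± 0.86 for Foxp3 (adjusted p = 0.0362), 3.10 ± 0.72 for C3 (adjusted p = 0.0321) and -2.03 ± 0.55 for Mki67 (adjusted p = 0.0336), with n = 3 in each of 4 groups. It did not pass for Cd8a at 4.20 ± 1.88 (adjusted p = 0.123), Gzmb at 4.91 ± 2.76 (adjusted p = 0.208), Vcam1 at 2.89 ± 1.19 (adjusted p = 0.0971) or Pmel at 0.31 ± 0.25 (adjusted p = 0.371).

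Among the lists, 14 were higher and 1 lower. Neuron (6.76, adjusted p = 4.53e-09) passed in 12 of 12 genes, oligodendrocyte (6.68, adjusted p = 4.71e-09) in 10 of 11, astrocyte (3.56, adjusted p = 7.36e-08) in 8 of 12 and microglia (3.18, adjusted p = 8.04e-06) in 8 of 11. Adjusted over the list alone these counts were 12, 11, 11 and 10. The cell cycle list (-1.90, adjusted p = 2.46e-13) was lower in 19 of 20 genes, and in 20 adjusted over the list alone. Complement (3.10, adjusted p = 8.94e-05) passed in 5 of 11, with 10 adjusted over the list alone, and T cell identity (3.70, adjusted p = 0.0107) in 1 of 16 by both counts, the adaptor gene Lat at 2.26 ± 0.57 (adjusted p = 0.0321). Checkpoint receptors (3, adjusted p = 0.003915) passed in 2 of 12, with 5 adjusted over the list alone, and regulatory T cell genes (2.40, adjusted p = 0.01105) in 2 of 8, with 3. With an estimated correlation the neuron, oligodendrocyte, astrocyte, microglia and cell cycle lists had adjusted p = 0.41, complement adjusted p = 0.569, and T cell identity adjusted p = 0.712. These were, for checkpoint receptors, adjusted p = 0.643 and, for regulatory T cells, adjusted p = 0.619, and fry called 7 lists. Also higher, each at adjusted p = 0.712 with an estimated correlation, were macrophage genes (2.42, adjusted p = 0.018, 5 of 14 genes), chemokines (3.28, adjusted p = 0.0166, 1 of 18), MHC class I (2.68, adjusted p = 0.0247, 0 of 18) and type I interferon (2.79, adjusted p = 0.0346, 0 of 20). Endothelial cell genes (1, 4 of 13) and immediate early genes (1.65, 4 of 11) were higher at adjusted p = 0.0107, and at adjusted p = 0.544 and 0.41 with an estimated correlation. Cytotoxic effector (3.98, adjusted p = 0.0573), interferon gamma (2.93, adjusted p = 0.0526) and MHC class II (4.01, adjusted p = 0.0666) did not pass. Miat, Sox1, Cnih3 and Otud7a had 0 reads in the intracranial-only therapy group and are given no fold.

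The interaction passed in 3505 genes, 1924 higher and 1581 lower, and in 0 with the neuron covariate. The count was likewise 0 without any of intracranial-only IgG replicates 2 and 3, intracranial-only therapy replicates 1, 2 and 3, both-tumor IgG replicate 1 and both-tumor therapy replicates 2 and 3. Without both-tumor IgG replicate 2 it passed in 2448. Without intracranial-only IgG replicate 2 the lists of T cell identity (0.517), checkpoint receptors (0.0756) and regulatory T cells (0.155) did not pass, nor did T cell identity without both-tumor IgG replicate 2 (0.0514). Chemokines (0.769), MHC class I (0.769), macrophage (0.223) and type I interferon genes (0.933) did not pass either without intracranial-only IgG replicate 2. MHC class I and type I interferon genes were also lost without intracranial-only therapy replicate 1 (0.0982 and 0.13) or 2 (0.0735 and 0.0973) or both-tumor IgG replicate 2 (0.171 and 0.22). Type I interferon genes were lost without both-tumor IgG replicate 3 (0.0635) or both-tumor therapy replicate 2 (0.0563), and macrophage genes without intracranial-only therapy replicate 1 (0.0649) or both-tumor IgG replicate 2 (0.0514). With the neuron covariate T cell identity, checkpoint receptors and regulatory T cells stood at adjusted p = 0.0865 and microglia at 0.101. The cytotoxic, interferon gamma and MHC class II lists passed without intracranial-only IgG replicate 1 (0.00497, 0.00344 and 0.00941) or 3 (0.00418, 0.00303 and 0.00784). So they did without intracranial-only therapy replicate 3 (0.00555, 0.000221 and 0.00726) or both-tumor IgG replicate 1 (0.0369, 0.0334 and 0.0471), and interferon gamma also without both-tumor therapy replicate 1 (0.0397) or 3 (0.0491). Across the 15925 genes, which are not independent replicates, log2 fold changes of both therapy comparisons, which share no library, correlated with Pearson r = -0.59, and 24.6% had the same sign. No gene passed in both, since 0 passed in intracranial-only mice.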

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

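The tests of a sample swap and of fewer tumor cells, the brain covariate made of the neuron, oligodendrocyte and astrocyte lists, and the 15 lists counted as immune, were chosen only after the results were seen. The effect of therapy differed between mice with both tumors and mice with the intracranial tumor only, by a test of the difference itself, for 3505 genes and 15 gene lists. With an estimated correlation 0 of these lists passed (smallest adjusted p = 0.41), and 0 genes passed with the neuron list as a covariate or when any of 8 of the 12 libraries was left out. Among the genes reported in every comparison, the difference of log2 fold changes was 7.35 for Snap25, 3.07 for P2ry12 and -2.03 for Mki67. Of 60 splits drawn from 200 possible ones, 1, the real split, gave as many interaction genes, and the highest of the others gave 0. That share lies under 0.05 for the count with all 12 libraries. It does not exclude chance, since the other splits mostly put libraries of both treatments together, which widens the spread within groups. Counts without 1 library were not split. For the other comparisons 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 858 and 0 for therapy in mice with both tumors, and 7231 and 0 for the extracranial tumor under therapy. They were 0 and 0 for therapy in intracranial-only mice, and 0 and 7 for the extracranial tumor under IgG. As many genes as in the real split came from 1, 1, 10 and 10 splits in that order.

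By group means of the list scores, the therapy libraries of mice with both tumors stood above their comparison groups in T cell, microglial and brain-tissue lists, though the neuron score of replicate 1 (4.35) lay below those of IgG replicates 1 and 3 with both tumors (4.56 and 5.02). Adjoining brain tissue as the whole source of the immune increase under therapy stays open. At the preset correlation 14 of 14 immune lists were still called higher with the neuron covariate and 13 with the brain covariate. The T cell identity median was 2.67 before, and 2.31 and 1.96 after, so much of that list's rise remained. But neither covariate holds microglial genes. Gene-wise, 0 genes passed with the neuron covariate, which inflated the variance of this contrast 1.39 times. Replicate 2 of the IgG mice with both tumors as the whole source is argued against by 12 of 14 lists called without it, but these list calls are at the preset correlation, and 0 lists passed with an estimated correlation (smallest adjusted p = 0.358). That library correlated at 0.987, 0.986 and 0.977 with the intracranial-only therapy libraries and at 0.933 and 0.917 with its own group. No intracranial-only therapy library was out of place as a swap partner (largest correlation difference -0.046), but libraries of other groups were not tried. Intracranial-only IgG replicate 2 correlated at 0.976 and 0.964 with both-tumor IgG replicates 1 and 3, and at 0.95 and 0.94 with its own group. A swap of those 2 libraries stays open, as does a wrong label of both-tumor IgG replicate 2 alone. But such a swap would leave both-tumor IgG replicate 2 apart in its new group. It correlated at 0.953 and 0.931 with intracranial-only IgG replicates 1 and 3, and its neuron score was -0.39 against 4.41 and 4.8. The weight of both-tumor IgG replicate 2 in the gene count stays open too. That count was 0 with the neuron covariate, 0 without this library and below 50 percent of 858 without any of 9 of the 12 libraries. For the genes of the extracranial tumor effect under therapy, brain tissue and the groups cannot be told apart: 0 genes passed with the covariate, which inflated the variance of the contrast 3.38 times, and 72.5% of the variance of the neuron score lay between groups, while a response to the extracranial tumor stays open.

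Cell cycle genes were lower with therapy in mice with both tumors, by a median of -1.47, but the list did not pass with an estimated correlation (adjusted p = 0.358). Fewer tumor cells in the tissue would lower pigment genes alike if each tumor cell kept its pigment expression, which was not tested. The median of the cell cycle list lay -1.40 from that of the pigment list, with a bootstrap SE of 0.09 over genes (2000 draws) that leaves out the spread between mice. Per library this difference was -1.58 ± 0.58 (SE, n = 3 per group, 95% interval -3.2 to 0.04, exact permutation p = 0.1, the smallest these groups can give), so it does not decide. The pigment score differed by 0.01 ± 0.11 (-0.31 to 0.33), which under that condition argues against a loss of tumor cells of that size. With the neuron list as a covariate the median was -1.03 (adjusted p = 3.42e-18 in camera at the preset correlation). Without replicate 2 of the IgG mice with both tumors it was -1.15 (adjusted p = 5.24e-18 likewise), which argues against that library as the whole source. The neuron covariate cannot decide on adjoining brain tissue, because the neuron list does not stand for all of it. In mice with both tumors oligodendrocyte scores were 5.18, 4.37 and 5.37 with therapy and 2.62, 0.42 and 3.89 with IgG. Neuron scores were 4.35, 6.25 and 5.88 with therapy and 4.56, -0.39 and 5.02 with IgG. A response of dividing cells to therapy stays open, and which cells the transcripts came from was not tested.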

How the results depend on the processing

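The robust edgeR fit and the mean of the neuron, oligodendrocyte and astrocyte lists (brain covariate) were chosen only after the results were seen, and all other alternatives before the data were examined. No paired analysis was possible because the labels carry no replicate numbers. Without 1 library a group keeps 2, and its spread is pooled with that of the other groups. Where a value changed, the cause was not tested, except that a covariate takes out the genes it is made of and inflates the variance of the contrast. In mice with both tumors the gene-wise result of therapy sits at the threshold, with a smallest adjusted p = 0.0498. The side of the threshold was kept in 1464 of the gene results of that comparison, 536 were weaker and 152 stronger. Results that passed in neither fit count as kept whatever their direction. For the extracranial tumor under therapy the kept, weaker and stronger results were 1799, 213 and 86, and for the interaction 1037, 473 and 35. In each fit of therapy in mice with both tumors where no gene passed, 38 named gene results were weaker.

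For therapy in mice with both tumors (858 genes), 0 genes passed with RLE size factors, 0 without the low-count filter, 0 in a fit of only the 2 groups compared, 0 with the neuron covariate and 0 with the brain covariate. DESeq2 called 3139, voom 5527, log2(FPKM + 1) 2630 and log2(FPKM + 0.1) 1759, and leaving out 1 library gave 0 to 2394. For therapy in intracranial-only mice (0 genes) DESeq2 called 1038 and the 2 groups alone 839, and leaving out 1 library gave 0 to 1002. For the extracranial tumor under therapy (7231 genes) both covariates gave 0, and leaving out 1 library 4710 to 8128. For the interaction (3505 genes) both covariates gave 0, and leaving out 1 library 0 to 4367.

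With an estimated correlation 0 lists passed in each of the 5 comparisons. The fry test called 8 lists for therapy in mice with both tumors, 0 in intracranial-only mice, 0 for the extracranial tumor under IgG and 7 for the interaction. For therapy in intracranial-only mice 3 lists passed with the neuron covariate and 2 with the brain covariate, and leaving out 1 library gave 5 to 18. It gave 5 to 24 for the extracranial tumor under IgG and 8 to 20 for the interaction.

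Directions of lists turned as follows, with adjusted p under the neuron and then the brain covariate. For therapy in mice with both tumors: neuron 0.525 and 2.84e-08, hypoxia and glycolysis 0.00984 under the brain covariate. For therapy in intracranial-only mice: homeostatic microglia 0.305 and 0.141, cell cycle 0.00622 and 0.0661, neuron 0.993 and 0.623, astrocyte 0.969 under the brain covariate. For the extracranial tumor under IgG: neuron 0.78 under the neuron covariate. For the extracranial tumor under therapy: hypoxia and glycolysis 0.507 and 0.224, pericyte and fibroblast 0.0377 and 0.0132, neuron 0.96 and 3e-04. For the interaction: pericyte and fibroblast 0.0104 and 0.00493, neuron 0.805 and 0.000801, homeostatic microglia 0.874 under the brain covariate.

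Directions of named genes turned as follows, as log2 fold changes. For the extracranial tumor under therapy with the brain covariate: Cnih3 -0.17, Esm1 0.28, Hoxb9 2.16, Snap25 -1.15, Syn1 -0.78, Sall1 -0.07, Cx3cl1 -1, Cldn5 -0.06, Ldha 0.06 and Car9 0.57. With the neuron covariate these were 0.99 for Hoxb9, -0.15 for Cx3cl1 and 0.18 for Car9. For the interaction with the brain covariate: Cnih3 -0.37, Slc17a7 -1.58, Snap25 -1.11, Slc1a3 -0.03, Rbfox3 -0.23, Syn1 -0.93 and Cx3cl1 -1.2. With the neuron covariate these were -0.01 for Slc17a7 and -0.34 for Cx3cl1.

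Leaving out 1 library turned the direction of some lists, here with the lowest and highest adjusted p. For therapy in intracranial-only mice these ran from 0.000238 to 0.995 for T cell identity, 0.00276 to 0.997 for NK cell, 0.00987 to 0.994 for dendritic cell, 2.59e-08 to 0.93 for interferon gamma response, 9.21e-06 to 0.99 for type I interferon response, 2.47e-07 to 0.995 for MHC class I presentation and 8.55e-05 to 0.99 for chemokines. For the extracranial tumor under IgG they ran from 1.56e-17 to 0.882 for cytotoxic effector, 0.000239 to 0.964 for homeostatic microglia, 8.68e-11 to 0.835 for monocyte and macrophage, 1.83e-29 to 0.984 for interferon gamma response, 2.94e-27 to 0.61 for MHC class I presentation and 9.31e-19 to 0.839 for chemokines. They also ran from 0.000239 to 0.916 for cell cycle, 2.51e-06 to 0.534 for neuron, 2.66e-08 to 0.568 for oligodendrocyte and 0.000729 to 0.611 for astrocyte. In the fits that turned for therapy in intracranial-only mice, adjusted p was 0.0245 for interferon gamma, 0.0184 for MHC class I and the lowest elsewhere. Under IgG it was 0.828 and 0.882 for cytotoxic effector, 0.984 for interferon gamma, and 0.567 and 0.61 for MHC class I. For chemokines it was 0.281, 0.101 and 0.839, and for macrophage genes 0.0415. It was 0.0021 for microglia, 0.00557 for cell cycle, 0.0094 for neuron, 0.0352 for oligodendrocyte and 0.0376 for astrocyte.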

Other observations

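The test of liver genes and the genes in it were chosen only after the results were seen, and the values per library are given with no test. Libraries of the same group differed widely in interferon gamma response genes, which mark cells exposed to that cytokine. The mean log2 CPM of this list was 1.2, 7.01 and 1.7 in the intracranial-only IgG libraries, 1.52, 2.62 and 6.42 in the intracranial-only therapy libraries, 5.77, 2.8 and 5.73 in the IgG libraries of mice with both tumors and 6.61, 8.4 and 8 in their therapy libraries. T cell identity genes had means of -2.04, 1.24 and -2.1, then -1.99, -1.84 and 0.38, then 0.73, -1.86 and 0.9, then 2.3, 3.22 and 3.27 in the same order. The B and plasma cell list, too small for the list test, had 2 of 3 genes higher with both tumors under therapy, with a median of 3.46.

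Transcripts of genes made mainly by the liver were present in every library. Albumin (Alb) ran from 51.2 to 152 CPM, and Fga and Fgb, which encode fibrinogen chains, had 4315 and 3368 reads over all libraries. A candidate explanation is 1 outside source of liver RNA or reads, which would keep the liver genes in 1 ratio in every library. For 24 genes the chi-square of their counts was 1.25 per degree of freedom (253 degrees of freedom), against a median of 37.1 and a lowest value of 13.4 in 100 sets of other genes with like totals. The ratio was thus nearer to constant than in those sets, but it departed from 1 fixed ratio beyond counting noise (permutation p = 0.0045, 2000 permutations), so a part from elsewhere stays open, and 2 further listed genes were left out because brain also makes them. The summed CPM of these genes ran from 147 in intracranial-only therapy replicate 3 to 434 in intracranial-only IgG replicate 1, and where such a source entered was not tested.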
